A study of Mus musculus with 4 samples.

How the data were processed

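Gene expression was measured on 4 one-colour Affymetrix arrays, 1 per sample, in Langerhans cells of mice. Langerhans cells are the antigen-presenting dendritic cells of the epidermis. TCDD (2,3,7,8-tetrachlorodibenzo-p-dioxin) is a ligand of the aryl hydrocarbon receptor (AhR), a transcription factor. Per the labels, 10 µg TCDD or its vehicle was injected into the peritoneum, cells were isolated after 24 h and sorted to a purity of 95%, RNA was extracted with Trizol, amplified with a MessageAmp kit and labelled with biotin. Amplification from the 3′ end makes the signal of a probe set depend on how far it lies from that end and on the length of the RNA.

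The deposited values are MAS5 signal intensities on a linear scale, 1 per probe set and array, and the submitters' processing notes name affy and MAS5 with versions not given in the sources used here. All 4 deposited intensity columns had a mean of 500 after the lowest and highest 2% of probe sets were removed, so the arrays had been scaled to a common trimmed mean. Detection calls and background settings are not given in the sources used here. The table held 22690 probe sets, of which 64 Affymetrix control probe sets were used only for RNA quality. Of the remaining 22626, 20380 had 1 gene symbol in the platform annotation, 691 had several and 1555 were unnamed here. Through gene IDs, 20351 of the single symbols matched a RefSeq mouse gene table (GRCm38.p6), and 0 symbols needed an update. That table served for names only, and the array files name no genome build, so no coordinates are given. Probe sets with several symbols were not named.

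Samples were grouped by their titles and descriptions into 2 controls and 2 TCDD samples. Replicates 1 of each group name no skin site in the labels and replicates 2 name back skin. The 2 controls also carry different experiment dates, and the TCDD descriptions give none. Site and experiment therefore cannot be told apart and are called the preparation. That arrays of the same replicate number share a site and an experiment is assumed. The labels of control 2 conflict: its title and description name a control, and its treatment protocol names TCDD. Title and description were followed, and fits without that array were run. Nothing in the labels says whether the arrays come from separate animals or pools, so p-values measure the spread between these samples, which may be technical.

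Signals were taken to log2 with no further normalization. The 13576 probe sets whose mean log2 signal lay at or above the 40th percentile (6.85, a geometric mean signal of 115) were tested with limma 3.58.1 in R 4.3.3, with treatment and preparation as additive terms, eBayes with a mean-variance trend and Benjamini-Hochberg adjustment at 0.05. This model leaves 1 residual degree of freedom per probe set, moderated across probe sets. The number of arrays limits the precision: the median standard error of a log2 difference was 0.364. A pairing check was made on the preparations: across probe sets, the log2 ratio of back skin to the other preparation in control and in TCDD had a Pearson's r of -0.18, so arrays of a labelled preparation did not deviate together.

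The fit was tested on simulated data: in 20 simulations of TCDD against control on 13576 probe sets, with 200 changed, it called 2.5% of the 2-fold, 53.0% of the 4-fold and 94.9% of the 8-fold changes, with 11.4 false calls per simulation, and 94.7% of its 95% intervals covered the true value. The simulated noise was drawn from the fit's own variance model, equal on all 4 arrays and independent between them. The real arrays differed in RNA quality, so these rates need not hold for them.

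A set of 26 gene lists (pathways, Langerhans cell functions and markers of other skin and blood cells) was fixed before the data were examined, as were all choices of design. A gene was represented by its brightest probe set with 1 symbol, which gave 8413 measured genes. Lists were tested with limma's camera at a preset correlation of 0.01, adjusted over the lists, and with an estimated correlation. Per preparation, a list's median log2 ratio was placed among 10000 random lists of the same size matched on expression in 20 bins. Such percentiles describe these arrays and carry no replicate error.

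Named genes followed a rule set beforehand. For TCDD it takes the 12 probe sets in each direction with the largest fold among those past 0.05 and of the same sign in both preparations, and fills open places in order of the smaller of the 2 within-preparation ratios. For the preparation it takes 8 in each direction likewise. It adds 12 genes chosen beforehand and up to 4 members per list with the largest log2 difference. Other genes are named where their count or value calls for it and are said to be chosen afterwards. The alternatives were quantile normalization, median centring, no filter or a stricter one, a floor, an offset, no variance trend, no preparation block, each array left out, 1 probe set per gene, the mean of a gene's probe sets, a threshold of 0.1, a smaller fold limit and an estimated correlation. A crossed pairing as a block, a variance trend in camera and camera's estimated correlation with each array left out were added after the data were seen.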

Results

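The data were 4 arrays of sorted mouse Langerhans cells taken 24 h after injection: control 1 and TCDD 1, whose labels name no skin site, and control 2 and TCDD 2 from back skin. The median signal was 164.9 on control 1, 180.8 on TCDD 1, 188 on control 2 and 172.8 on TCDD 2. Epcam, an adhesion molecule of Langerhans cells, read 8717 and 10032 on controls 1 and 2 and 7541 and 8362 on TCDD 1 and 2. Csf1r, the receptor for the growth factors that maintain these cells, was named after its values were seen and read between 8469 and 11699.

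RNA quality differed between arrays. The ratio of 3′ to 5′ signal of the actin control probe sets was 49.7 on control 1, 3.48 on TCDD 1, 4.64 on control 2 and 7.71 on TCDD 2. The corresponding Gapdh ratios were 106.8, 9.55, 11.9 and 15.9. Across the 13576 tested probe sets, which are not replicates, Pearson's r between log2 signals was lowest for the 2 controls (0.915) and highest for TCDD 1 and control 2 (0.960). It was 0.933 for control 1 and TCDD 1, 0.947 for control 2 and TCDD 2, 0.941 for control 1 and TCDD 2 and 0.957 for the 2 TCDD arrays.

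The main comparison asked which genes of Langerhans cells differ after TCDD. The classic AhR target genes showed no common direction. Cyp1a1, the monooxygenase most often used to read AhR activity, had a low signal throughout, 182.8 on control 1, 94.9 on TCDD 1, 117.8 on control 2 and 190.7 on TCDD 2, a TCDD minus control log2 difference of -0.13 ± 0.51 (SE, n = 2 per group). Ahrr, the AhR repressor, read 1861 and 959.7 in the controls and 1112 and 1049 after TCDD (-0.31 ± 0.37). Tiparp, a TCDD-inducible ADP-ribosyltransferase, read 1499 and 1792 in the controls and 2306 and 1808 after TCDD (0.32 ± 0.35) by its brightest probe set. Its other tested probe sets had log2 ratios of 1.37 and 1.40 with no site named but -0.58 and -0.49 in back skin. None of these differences passed the test (limma, adjusted p = 0.9999 for each).

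The remaining xenobiotic genes gave similar intervals. Nqo1, a quinone reductase, differed by 0.07 ± 0.37. The brightest probe set of Cyp1b1, a monooxygenase related to Cyp1a1, differed by -0.59 ± 0.48 and another tested one by 0.09 ± 0.52, so its probe sets disagreed in sign. Ahr itself differed by -0.36 ± 0.41, with log2 ratios of TCDD to control of 0.31 in the preparation with no site named and -1.03 in back skin. Arnt, the dimerization partner of AhR, lay below the expression filter at signals from 80.5 to 146.5 and was not tested. Of 10 measured AhR target genes, 2 were higher after TCDD in both preparations, 2 lower in both and 6 went opposite ways. In the list of 7 AhR pathway components, 0 were higher in both preparations and 1 was lower in both. The signs of Cyp1a1 and Ahrr turned without control 1 (0.19 and 0.17), Cyp1a1 also turned without TCDD 1 (0.38), Nqo1 turned without control 2 (-0.41) or TCDD 1 (-0.05), and Ahr without TCDD 2 (0.0012).

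**Figure D1:**
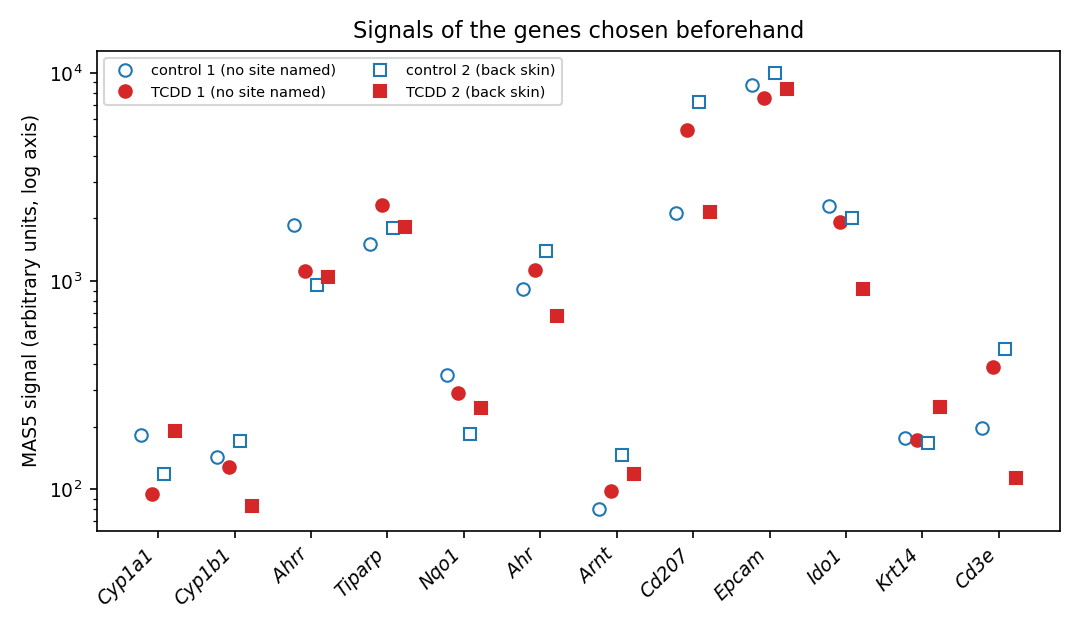
MAS5 signal (arbitrary units, log axis) of 12 genes chosen beforehand on each of the 4 arrays, 1 point per array, open for control and filled for TCDD, circles for the preparation with no site named and squares for back skin. Cd207 and Cd3e are higher on TCDD 1 and control 2 than on control 1 and TCDD 2, whereas Epcam lies between 7541 and 10032 on all 4.

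Over all probe sets, 0 of 13576 differed between TCDD and control at an adjusted p under 0.05 (limma, smallest adjusted p 0.9999). At an unadjusted p under 0.05 there were 199, of which 123 were higher and 76 lower after TCDD, where 678.8 would be expected by chance. The median 95% interval reached 0.83 log2 units to either side. The error of this fit comes from the difference of control 2 and TCDD 1 from control 1 and TCDD 2. That difference had an SD of 0.456 across probe sets, against 0.353 for TCDD minus control. The p-values may thus be too large. Blocking on that split in place of the preparation, chosen after the data were seen, gave 10 probe sets past 0.05. The count depended on single arrays, in fits that assume that the lone array of a group varies like the others: 12 probe sets passed without control 1 and 285 without control 2, the sample with conflicting labels. Of the 285, 266 were higher after TCDD, and 1 probe set was common to both fits.

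Il1b, the inflammatory cytokine interleukin 1 beta, read 3882 and 4178 in the controls and 6031 and 9509 after TCDD (0.91 ± 0.32). Il1r1, its receptor, also higher after TCDD in both preparations, read 145.2 and 109.9 in the controls and 315.3 and 299 after TCDD (1.28 ± 0.38). C1qa, a chain of complement component C1q, differed by 2.27 ± 0.59, with 25.2 and 126 in the controls and 260.9 and 284.3 after TCDD. Ebi3, a subunit of interleukins 27 and 35, differed by 1.19 ± 0.47 from signals of 35.8 and 165.4 in the controls. The immunoglobulin light chain segment Igkv9-120 differed by 1.98 ± 0.49, from 54.3 and 75.5 in the controls to 323.9 and 197.8 after TCDD. None of these genes passed the test over all 4 arrays (limma, adjusted p = 0.9999 for each). Without control 2 the log2 difference was 3.43 for C1qa and 2.22 for Igkv9-120, each against control 1 alone. On control 1 the 25.2 of C1qa and the 35.8 of Ebi3 lay below that array's 20th percentile signal of 36.6, so their folds are not exact.

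Other genes with higher values after TCDD in both preparations were Msx1 and Foxn4, which encode developmental transcription factors, Coil, Gid4, Prelid3a, Tufm, the mitochondrial elongation factor, Pcbd1 and Acbd3. The log2 difference was 1.26 ± 0.36 for Tufm and 0.90 ± 0.34 for Acbd3. Prelid3a passed the test without control 1 (2.08, limma adjusted p = 0.0451), from signals of 177.3 and 79.5 in controls 1 and 2 and 344.9 and 325.4 after TCDD. Genes with lower values in both were headed, by the naming rule, by Lalba, which encodes the milk protein alpha-lactalbumin (-1.74 ± 0.45), and Timm8b, a mitochondrial import chaperone (-1.59 ± 0.41). Il1f10, an interleukin 1 family member (-1.45 ± 0.43), Itgb7, an integrin chain of mucosal leukocytes (-1.31 ± 0.41), and Lgr5, a hair follicle stem cell marker (-1.47 ± 0.47), also belonged to this set. The other genes were Dmbx1, Dyrk1b, Grin2b, Bcam, Pkdcc, Neurod2 and Bves, between -1.84 for Grin2b and -1.14 for Bves. Dyrk1b passed the test without control 1 (-2.02, limma adjusted p = 0.0482), from 294.9 and 516.7 in controls 1 and 2 and 114.9 and 140.3 after TCDD. Many of these genes had signals close to the filter: Lalba read 186 and 301.9 in the controls and 50.7 and 98.6 after TCDD.

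The 2 log2 ratios of TCDD to control, each from its own pair of arrays, ran against each other across probe sets. Cd207, which encodes langerin, the lectin that defines Langerhans cells, read 2119.9 on control 1 and 5343 on TCDD 1, but 7211 on control 2 and 2155 on TCDD 2, log2 ratios of 1.33 and -1.74. Pearson's r between the ratios was -0.25 and Spearman's rho -0.26 over 13576 probe sets, which are not independent replicates. At least 2-fold in both preparations, 36 probe sets went the same way (15 up and 21 down) and 145 went opposite ways. Of the 145, 111 were higher after TCDD in the preparation with no site named and lower in back skin, and 34 the reverse. Without any effect of TCDD, both kinds would be equally frequent if the arrays differed at random.

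**Figure D2:**
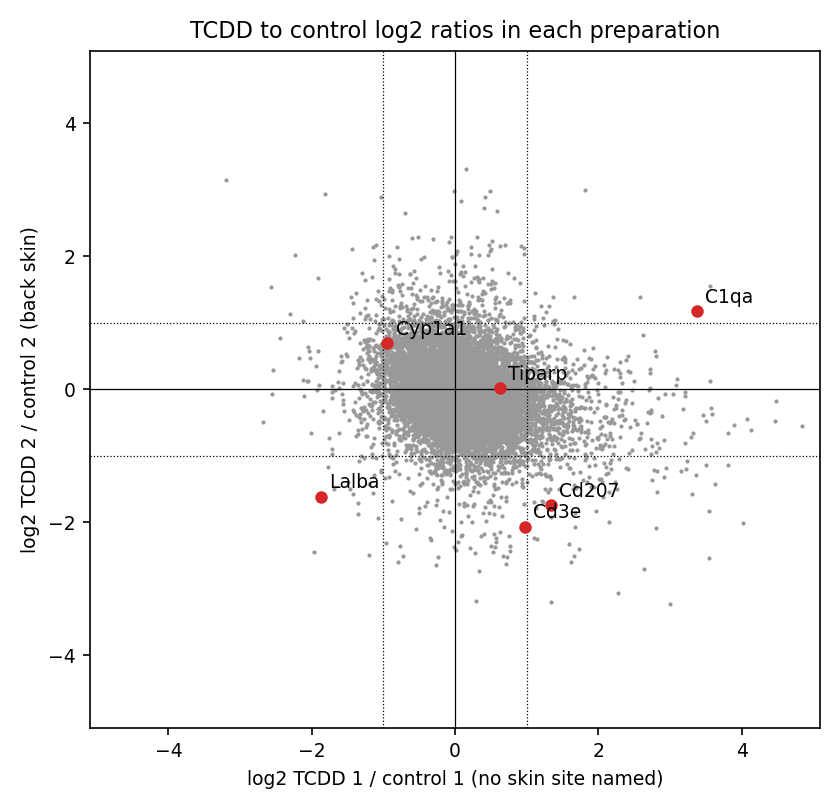
Log2 ratio of TCDD 1 to control 1 (horizontal axis) against log2 ratio of TCDD 2 to control 2 (vertical axis), 1 grey point for each of 13576 tested probe sets, with dotted lines at 2-fold and 6 genes in red. The cloud tilts from upper left to lower right (r = -0.25); Cd207 lies at 1.33 and -1.74.

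Among the gene lists, only the genes of glycolysis and hypoxia passed camera's test for TCDD (adjusted p = 0.0022), a call lost with an estimated correlation (camera, p = 0.358, adjusted p = 0.937). Of 17 measured members, 10 were higher after TCDD in both preparations, 0 lower in both and 7 went opposite ways, with a median log2 difference of 0.22, and 0 passed the test singly, over all genes or adjusted over the list alone. Tpi1, triosephosphate isomerase, read 1821 on control 1 and 8768, 8280 and 10118 on TCDD 1, control 2 and TCDD 2 (1.28 ± 0.46). Bnip3, a hypoxia-induced mitophagy receptor, read 593.8 on control 1 and 3452, 2897 and 2019 on the others (1.01 ± 0.62). Hk1, a hexokinase, differed by 0.75 ± 0.35 and P4ha1, a collagen prolyl hydroxylase subunit, by 0.65 ± 0.43. Without control 2, Tpi1 (2.37, limma adjusted p = 0.00014) and Bnip3 (2.15, limma adjusted p = 0.001) passed.

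The list's median log2 ratio was 0.45 in the preparation with no site named, the 99.97th percentile of matched random lists, and 0.04 in back skin, percentile 53.2. It was 0.44 in control 2 over control 1, the 99.8th percentile, and 0.46 in TCDD 2 over control 1, the 99.99th. Without control 1, the array with the highest 3′ to 5′ ratios, the list's median was 0.04 (camera, adjusted p = 0.697), and without TCDD 1 it was 0.12 (camera, adjusted p = 0.0834).

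**Figure D3:**
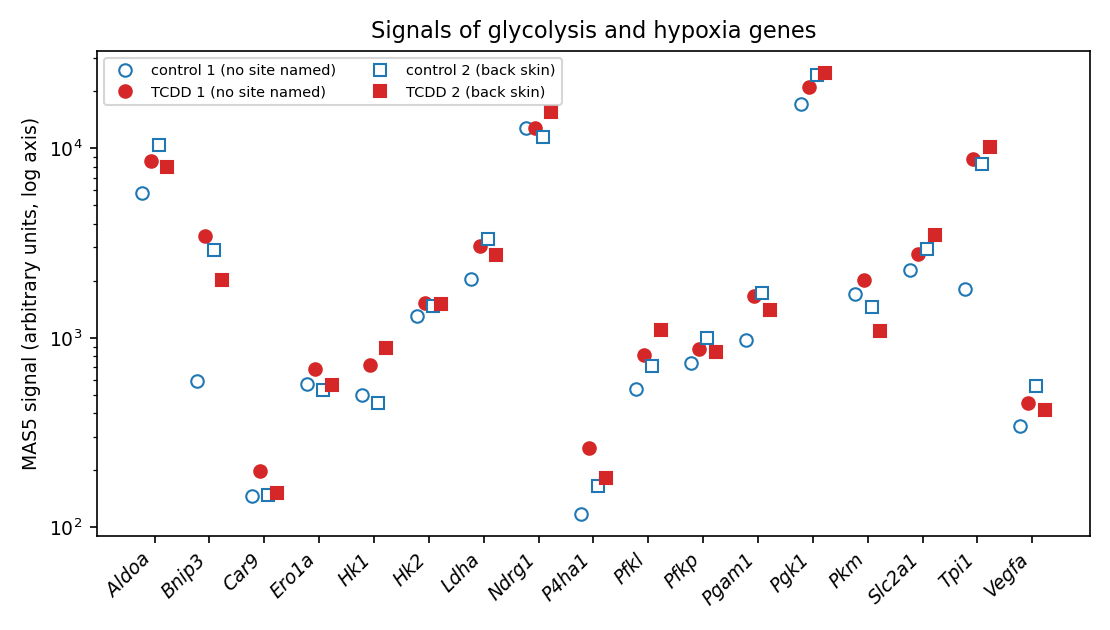
MAS5 signal (arbitrary units, log axis) of the 17 measured glycolysis and hypoxia genes on each array, open for control and filled for TCDD, circles for the preparation with no site named and squares for back skin. Tpi1 and Bnip3 stand lowest on control 1, at 1821 and 593.8, and above 2000 on the other 3 arrays.

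Markers of T cells, which include the dendritic epidermal T cells that share the epidermis with Langerhans cells, differed most between the preparations. Of 12 measured markers, 10 were higher after TCDD in the preparation with no site named and lower in back skin, 1 was lower in both and 0 were higher in both. Cd3e, a chain of the T cell receptor complex, read 197.5 on control 1, 386.9 on TCDD 1, 471.3 on control 2 and 112.7 on TCDD 2, and Cd3g, another chain that was named after its values were seen, read 71, 234.3, 471.4 and 89.5 in that order. Klrk1, the activating receptor NKG2D, read 47, 220, 288.1 and 109.4, and Cd247 differed by -0.70 ± 0.45. Of these markers, 1 (Thy1) is also in the list of fibroblast and endothelial markers. The median log2 ratio was 0.43 in the preparation with no site named, percentile 98.2, and -1.20 in back skin, below all 10000 random lists. Over the 4 arrays the list gave a median of -0.21 (camera, adjusted p = 0.497, and p = 0.674 with an estimated correlation), with 0 members past the test over all genes or adjusted over the list alone. The list's median depended on single arrays: it was -0.90 without control 1 and -0.59 without TCDD 1, but 0.19 without control 2 and 0.13 without TCDD 2. Each of these fits leaves a lone array in a group, and with an estimated correlation the list did not pass in any of them.

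**Figure D4:**
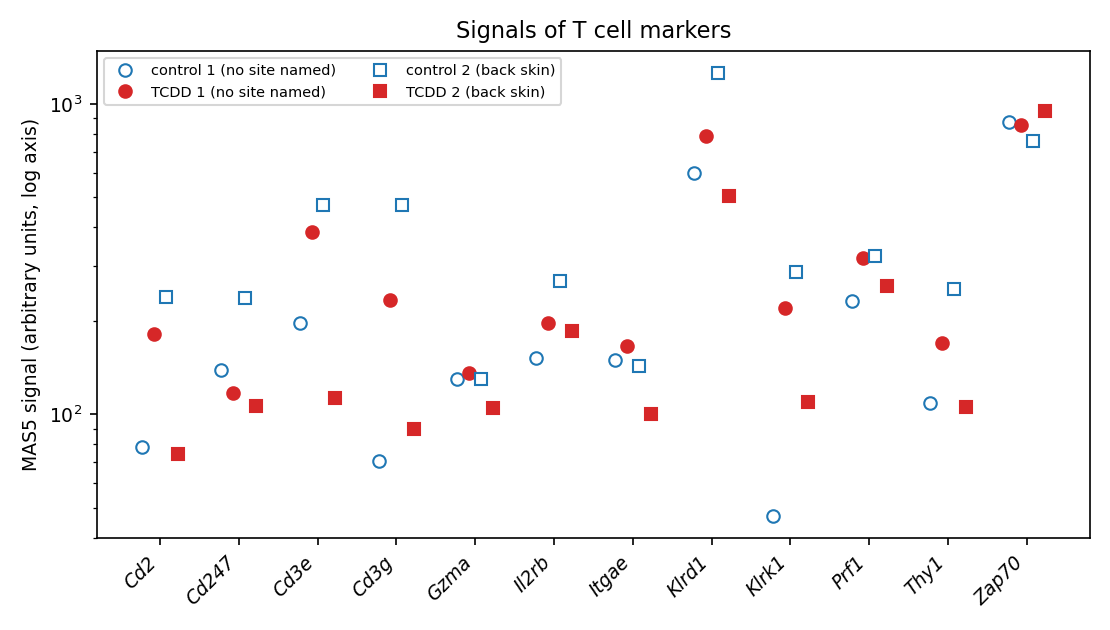
MAS5 signal (arbitrary units, log axis) of the 12 measured T cell markers on each array, open for control and filled for TCDD, circles for the preparation with no site named and squares for back skin. Cd3e, Cd3g, Cd2 and Klrk1 are higher on TCDD 1 and control 2 than on control 1 and TCDD 2; Cd3e ranges from 112.7 to 471.3.

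None of the other lists passed camera's test at 0.05, and in each of them 0 members passed the test over all genes or adjusted over the list alone. The genes of Langerhans cell identity had a median log2 difference of 0.01 and a mean of -0.02: of 24 measured, 5 were higher and 7 lower in both preparations. Fcer1g, the Fc receptor gamma chain, differed by -0.78 ± 0.36, and H2-Eb1, a class II chain, read 1404 on control 1, 5980 on TCDD 1, 7042 on control 2 and 3972 on TCDD 2; without control 2 it passed the test (1.80, limma adjusted p = 0.0046). Antigen processing and presentation genes had a median ratio of 0.21 (99.8th percentile) with no site named and -0.05 (percentile 15.1) in back skin, and of 0.29 (99.8th percentile) in control 2 over control 1, with 9 of 25 higher and 2 lower in both. Of 23 maturation and costimulation genes, 4 were higher and 2 lower in both. Ccl5, a chemokine of activated cells, read 13766 on control 1, 4179 on TCDD 1, 7913 on control 2 and 8229 on TCDD 2.

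For the regulators of tryptophan and retinoid metabolism, 2 of 11 were higher and 3 lower in both preparations. Ido1, the tryptophan-degrading enzyme of tolerogenic dendritic cells, read 2298 and 1999.6 in the controls and 1924 and 915.2 after TCDD (-0.69 ± 0.37), and its relative Ido2 differed by -0.91 ± 0.46. Rarg, a retinoic acid receptor, read 54.2 and 241.6 in the controls and 306.4 and 264.7 after TCDD (1.32 ± 0.56). Of 17 inflammatory cytokines and chemokines, 4 were higher, led by Il1b, and 3 lower in both, with a median of 0.05 and a mean of -0.01. Of 16 NF-kB targets, 1 was higher and 7 were lower, and of 16 interferon-stimulated genes, 2 were higher and 5 lower, with Bst2 (1.63 ± 0.55) and Ifi35 (1.22 ± 0.51) among the former and Oas2 (-0.84 ± 0.44) among the latter. Of 14 NRF2 and glutathione genes, 0 were higher and 5 lower in both, and Keap1 differed by 0.49 ± 0.38. Bst2 passed without control 1 (2.63, limma adjusted p = 0.0399), and Ifi35 (2.35, limma adjusted p = 0.00025) and Rarg (2.39, limma adjusted p = 0.0023) passed without control 2. Bst2 read 43.2 on control 2 and 172.9, 259.4 and 276.7 on control 1, TCDD 1 and TCDD 2, and Ifi35 read 85.7 on control 1 and 432.7, 410.7 and 439.3 on TCDD 1, control 2 and TCDD 2, so each call rested on a low value of the remaining control.

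Cholesterol and lipid synthesis genes had a median ratio of -0.27 with no site named (3.89th percentile) and 0.35 in back skin (99.88th percentile), and 12 of 17 were lower in the former and higher in the latter. In control 2 over control 1 their median was -0.51 (0.09th percentile), and in TCDD 2 over TCDD 1 it was 0.26 (98.95th percentile). Scd2, a fatty acid desaturase, had ratios of -0.62 and 1.74. Fdps, farnesyl diphosphate synthase, was higher in both (0.97 ± 0.35) and passed without control 2 (1.38, limma adjusted p = 0.0217), with 199.6 and 351.5 in controls 1 and 2 and 491.4 and 550.1 after TCDD. Their median over the 4 arrays was -0.01 and their mean 0.10. The list's median was 0.23 without control 1, but -0.12 without control 2 and -0.09 without TCDD 2. Over the 4 arrays it did not pass with an estimated correlation (camera, adjusted p = 0.937). Of 21 immediate early genes, 6 were higher, Junb by 0.69 ± 0.34 and Klf4 by 0.54 ± 0.34, and 1 was lower in both. The unfolded protein response had 5 of 19 higher and 4 lower (median -0.02, mean 0.09), oxidative phosphorylation 8 of 37 higher and 5 lower, ribosomal proteins 3 of 28 in each direction (median -0.01, mean 0.00), cell cycle 2 of 17 higher and 3 lower, and apoptosis and p53 targets 2 of 16 higher and 5 lower.

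Of the markers of other cells, those of melanocytes came closest to a call: 6 of 10 were lower and 1 was higher in both preparations, with a median of -0.28 (camera, adjusted p = 0.115). Tyrp1, a pigment enzyme, differed by -0.81 ± 0.47 and Pmel, a melanosome protein, by -0.71 ± 0.42. The melanocyte list's median was -0.31 without control 1. With an estimated correlation the list gave no call over the 4 arrays (camera, adjusted p = 0.937). Keratinocyte markers were 2 of 12 higher and 2 lower, with Krt14, the basal keratin, at 176.6, 172.6, 166.1 and 249.5 on control 1, TCDD 1, control 2 and TCDD 2. Hair follicle markers were 2 of 7 higher and 1 lower (median 0.04, mean -0.17). Fibroblast and endothelial markers were 4 of 10 higher and 2 lower, mast cell, granulocyte and monocyte markers 4 of 10 higher and 0 lower, and B cell, erythroid and platelet markers 1 of 5 higher and 0 lower. Among the sex-linked genes 2 were measured, too few for a test. The brightest probe set of Xist read 5414.5 on control 1 and 8270.2, 10758.6 and 6577 on TCDD 1, control 2 and TCDD 2. Its other tested probe set, named after its values were seen, read 423.4 on control 1 and 4663, 2442 and 1867 on the others in that order, and passed for TCDD without control 2 (2.80, limma adjusted p = 0.00018).

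**Figure D5:**
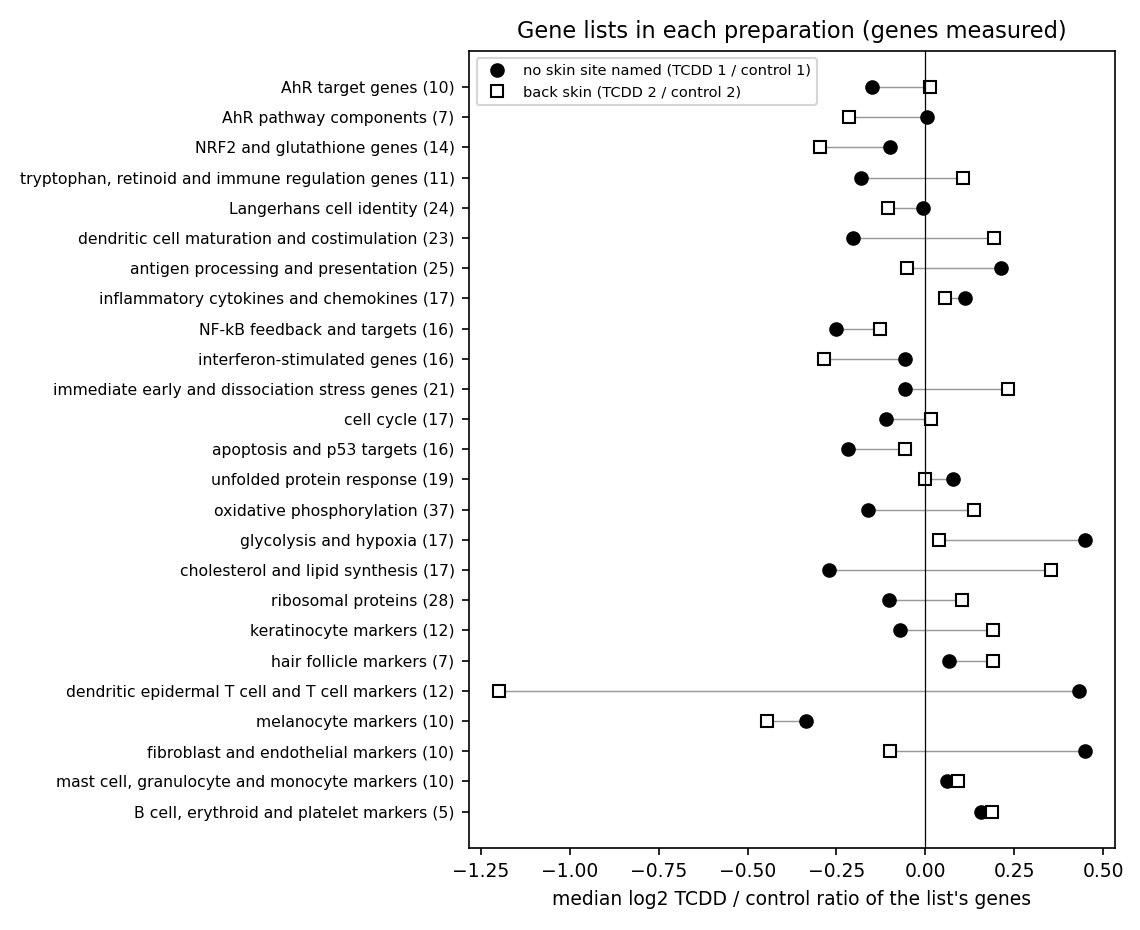
Median log2 ratio of TCDD to control of each tested gene list (horizontal axis), filled circles for the preparation with no site named and open squares for back skin, with the number of genes measured in brackets. T cell markers lie at 0.43 and -1.20, and cholesterol and lipid synthesis genes at -0.27 and 0.35.

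The comparison of back skin with the other preparation asked how the origin of the cells, or the experiment, was reflected in expression. Of the named genes, Ebi3 had the largest value for back skin (log2 difference 2.01 ± 0.47), with 35.8 and 93.6 on the arrays with no site named and 165.4 and 328.2 in back skin. The 35.8 on control 1 lay below that array's 20th percentile signal of 36.6, so this fold is not exact. Ets1, a lymphoid transcription factor, had the lowest (-1.96 ± 0.42), from 386.9 and 271.9 to 129.4 and 53.6. Ltf, the granule protein lactoferrin, read 284.3 and 301.6 against 78.4 and 123.8. The other genes with higher values in back skin were Atg2a, an autophagy gene, Bves, Stc1, Clps, Nol12, Nrbp2 and Mgmt, a DNA repair enzyme. Those with lower values were Surf6, Nbea, Msx1, Mtrex, Tmem186 and Plppr2.

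None of these genes passed the test: 0 of 13576 probe sets did (limma, smallest adjusted p 0.9994), with 274 at an unadjusted p under 0.05, 142 higher and 132 lower in back skin. Without TCDD 1, 89 probe sets passed, 88 of them higher in back skin, and 87 of the 89 were also among the 285 for TCDD without control 2. Control 1 is the lone array in both fits. No gene list passed camera's test for the preparation (smallest adjusted p 0.318). Adjusted over the list alone, 1 member passed, Ltf in the list of mast cell, granulocyte and monocyte markers, and 0 did in the other tested lists. The log2 ratios of back skin to the other preparation within control and within TCDD had an r of -0.18 (rho -0.16), with 33 probe sets at least 2-fold the same way and 145 opposite ways. At least 2-fold differences numbered 1663 between the 2 controls and 579 between the 2 TCDD arrays, against 1159 and 839 between TCDD and control with no site named and in back skin.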

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

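The test of further T cell genes over all 4 arrays was set before its result was seen; the other tests in this part were chosen afterwards. Each of these results is a ratio of TCDD to control arrays that went one way with no skin site named and the other way in back skin. The difference was not tested beside the effects of TCDD and preparation, since that model has no residual degrees of freedom. It was tested over all probe sets by a fit of the split of control 2 and TCDD 1 from control 1 and TCDD 2 without those terms. For gene lists the difference was placed among matched random lists, which carries no replicate error.

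The T cell markers had a median log2 ratio of 0.43 with no site named and -1.20 in back skin. More T cells among the sorted cells on control 2 and TCDD 1 is a candidate explanation, although the labels state a sorting purity of 95%. A second list of 14 measured T and natural killer cell genes had a median crossed difference of 0.17, at the 82.4th percentile of matched random lists. A percentile inside the middle 95% had been set beforehand as counting against more T cells, so the test set beforehand counted against them. Of the members, 10 were higher and 4 lower. Resampling them, a step chosen afterwards over genes that are not replicates, gave a 95% interval of the median from -0.15 to 0.35. The interval holds values of both signs and the random lists' upper limit of 0.31, but not the markers' 0.65. The result against more T cells was thus not beyond that spread, and the second list leaves them open. For TCDD over control that list lay at percentile 55.0 with no site named (0.05). In back skin it lay at the 1.99th percentile (median -0.42), just past the random lists' lower limit of -0.41. No spread over the members was taken there, so fewer T cells on TCDD 2 than on control 2 stay open. Its members were mixed: Txk (log2 ratio 2.14), Rasgrp1 (0.80), Eomes (0.53), Icos (0.42) and Fyb (0.28) were higher on TCDD 2. The other members were lower there. Il7r read 8960 on control 2 and 6039 on TCDD 2, but also 7876 on control 1 and 7767 on TCDD 1, all far above the signals of Cd3e. Cd3e and Cd3g read 471.3 and 471.4 on control 2 and 112.7 and 89.5 on TCDD 2, but belong to the first list and add no separate support. For RNA length, the markers had a median of 0.80 for the mean of control 2 and TCDD 1 minus TCDD 2. For TCDD 2 minus control 1 it was -0.06, a signed difference of 0.86. That passes the limit, chosen afterwards, that counts against RNA length as read by the actin ratio. The ratio was 49.7 on control 1 and 7.71 on TCDD 2, yet the markers were by median not lower on control 1. With median signals of 144.2 on control 1 and 108.1 on TCDD 2 they lay near the filter there, so RNA length stays open. A response to TCDD that differs between preparations is open and untested.

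Cd207 had log2 ratios of 1.33 and -1.74 and so followed the T cell markers across the arrays.

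The ratios of TCDD to control opposed each other, with 145 probe sets at least 2-fold apart in opposite ways. Preparations crossed between the labels may account for this: crossed pairs of arrays correlated more than labelled pairs by a mean r of 0.0104, which restates the opposed ratios and so lends this no support. RNA length or amplification may also account for it, since the lowest actin 3′ to 5′ ratio of control 1 and TCDD 2 was 1.66 times the highest of control 2 and TCDD 1. The split of control 2 and TCDD 1 from the other arrays gave 2 probe sets past 0.05 (limma, adjusted), 1 of Lasp1 (-3.17) and 1 with no name here (3.12), and 1389 at an unadjusted p under 0.05, against 0 and 220 for TCDD and 0 and 409 for the preparation, each fitted alone. Opposed ratios by themselves enlarge this split, so the larger counts restate them. With 1 array per cell of the design, crossed labels, RNA length or amplification and a preparation-dependent response to TCDD cannot be told apart.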

How the results depend on the processing

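The crossed pairing, the variance trend in camera and the estimated correlation with an array left out were chosen after the data were seen. The 0 probe sets past 0.05 for TCDD and for the preparation stayed at 0 under each normalization, filter, floor, offset and variance model, with 1 probe set per gene and without a replicate block; a threshold of 0.1 also gave 0 for TCDD. Leaving out each array in turn, the counts ranged from 0 to 285 for TCDD and from 0 to 89 for the preparation. With the crossed pairing as a replicate block, 10 probe sets passed for TCDD and 0 for the preparation, and 1 list passed. The number of lists past 0.05 was 1 in the other settings, 1 to 3 with an array left out and 0 with an estimated correlation, on all arrays or with each left out. Besides glycolysis and hypoxia, the lists past 0.05 with an array left out were T cell markers, cholesterol and lipid synthesis, and melanocytes. Each such fit leaves a lone array in a group. The r between the TCDD ratios was -0.12 with no filter. The probe sets going the same way and opposite ways numbered 615 and 927 with no filter, 3 and 66 with the 60th percentile filter, 13 and 89 with the offset, and 218 and 827 with a 1.5-fold limit. The cause was not tested, apart from the larger or smaller number of probe sets that each filter or limit admits. Of 347 list results, 30 changed camera's direction, which can differ from the sign of the list's median. Of 396 values of genes named for TCDD, 10 changed sign, and of 178 for the preparation, 0 did. Median centring took out of the TCDD ratios an offset between array medians of 0.13 with no site named and of -0.12 in back skin. Fitted without the replicate block for the preparation, 0 probe sets passed in either comparison and the list calls stayed on their side of 0.05. Low signals limit the fold of dim genes, since detection calls were not used here.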

Other observations

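The tests of the glycolysis list were chosen after its result was seen, and the genes named in this part were chosen after their values were seen.

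The probe sets called for TCDD when control 2 was left out were led by genes that were low on control 1 alone. Tmem234 read 42.6 on control 1 and 946.6, 873 and 776.3 on TCDD 1, control 2 and TCDD 2. Cdkn1a, the cell cycle inhibitor p21, read 833.3 against 7588, 7967 and 6513, Klf6, an early response transcription factor, 69.1 against 812.1, 777.1 and 844.5, and Mif, a macrophage cytokine, 454.3 against 3148, 3089 and 4589.

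The 12 probe sets called when control 1 was left out comprised 11 with higher and 1 with lower values after TCDD. Ogt, the O-GlcNAc transferase, read 33.3 on control 2 and 120.9, 425.6 and 265.8 on control 1, TCDD 1 and TCDD 2, and Btf3l4 read 38 against 326.9, 325 and 299. Mtor, the growth-regulating kinase, read 73.7 against 202.9, 288.9 and 344.6.

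The glycolysis and hypoxia list, the only one past the list test for TCDD and not past it with an estimated correlation (camera, adjusted p = 0.937), may reflect low values of the array control 1: control 2 over control 1, with neither sample called TCDD by its title, put the list at the 99.79th percentile of matched random lists. The median log2 ratio in back skin lay below that in the other preparation by a difference of -0.412, which counts against an equal effect of TCDD in both only if control 2 was untreated. TCDD given to control 2, as its treatment protocol states, could leave control 1 as the only vehicle sample: the list's median was 0.46 in TCDD 2 over control 1 (99.99th percentile), 0.45 in TCDD 1 over control 1 and 0.44 in control 2 over control 1. The AhR target genes lay at the 43.7th percentile in control 2 over control 1, but also at the 18.6th in TCDD 1 over control 1 and the 0.48th in TCDD 2 over control 1. These genes did not mark the labelled TCDD arrays, so a treated control 2, with an equal effect of TCDD, and low values of control 1 from its RNA cannot be told apart by them.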
